A study of Sus scrofa with 13 samples.

How the data were processed

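RNA of biceps femoris muscle from 13 German Landrace pigs was measured on whole-transcript expression arrays, 1 array per animal and none pooled. The labels give 4 groups by genotype and age: DMD KO at 2 days (n = 4), WT at 2 days (n = 3), DMD KO at 3 months (n = 3) and WT at 3 months (n = 3), described as biological replicates. RNA was extracted with Trizol and labelled with biotin by the kit of the array maker. The arrays were processed with Affymetrix Power Tools, per the submitters' processing notes. Its version, the summary method, the background correction and the normalization are not given in the sources used here.

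The deposited table holds 21893 probe sets by 13 arrays in values that were taken as log2 levels, since they run from 2.81 to 13.8 with several decimals, as log2 summaries of array intensities do. The log base is inferred from the values. That the arrays were normalized before deposit is an inference from their close medians and quartiles. Their 95th percentiles were less close, from 9.21 on WT replicate 3 at 2 days to 9.83 on DMD KO replicate 3 at 3 months. The bright ends of the arrays were thus not brought fully into line. The medians were 7.36, 7.34, 7.36 and 7.35 for DMD KO replicates 1 to 4 at 2 days, 7.35, 7.37 and 7.36 for WT replicates 1 to 3 at 2 days, 7.38, 7.37 and 7.32 for DMD KO replicates 1 to 3 at 3 months, and 7.35, 7.38 and 7.33 for WT replicates 1 to 3 at 3 months. Deposited values were used as they are, with no filter and no further normalization. Arrays give no counts, so the number of arrays limits the precision.

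Gene names came from the annotation of the series' probe sets. Of the probe sets 11028 carried 1 symbol, 418 several and 10447 none, so almost as many probe sets went unnamed as were named. The named ones stood for 10283 genes, of which 694 had several probe sets. For 10761 probe sets the symbol was looked up by gene number in a table of current names, which updated 5 symbols. The table holds 485 probe sets whose values repeat those of another one. A gene was represented by the probe set with the highest mean over all 13 arrays. Probe sets without a symbol or with several counted among the probe sets tested and were not named or used in lists.

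Every probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) over the 4 groups together, which leaves 9 residual degrees of freedom. Contrasts were DMD KO minus WT at each age, 3 months minus 2 days in each genotype, and the interaction, the genotype difference at 3 months minus that at 2 days. Tests were two-sided, p was adjusted by Benjamini-Hochberg over the probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. Replicate numbers were not used as pairs, since nothing in the labels ties animals of the same number. SE is the moderated standard error of limma, and SD is the spread within a group.

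A total of 46 gene lists (pathways, complexes and cell type markers) was fixed, and the 44 with at least 3 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 44 lists. Camera compares the genes of a list with all other named genes. Each list test was repeated with a correlation estimated per list, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. For each list the called members were counted with p adjusted over all probe sets and with p adjusted over the list alone. The lists for Y-linked genes and for the inactive X chromosome had too few measured genes and were not analysed here. The list test of the age comparison in DMD KO was not among the tests fixed at the start.

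The groups, contrasts, tests, gene lists and the rule for naming genes were chosen before the data were examined. The rule named the dystrophin complex in every comparison. For each genotype comparison it named the 10 genes with the largest rise and the 10 with the largest fall among called genes with 1 symbol and no overlap between the values of the groups, for the age comparison in WT the same with 8 and 8, and for the interaction 5 and 5. Of each called list it named up to 4 called members along the list's direction and up to 2 against it, or up to 2 members by value where none was called. The text gives a part of these. Effect correlations were computed across probe sets and across named genes, and the overlap of called genes was set against the product of the counts over the number of genes.

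The leading axis of the spread within groups was the first principal component of the values after the group means were taken away. The score of an array was the projection of its values, group mean included, on that component, centred over the arrays. Alternatives fixed at the start were fits on the groups of a contrast alone, eBayes with trend and robust settings, quantile normalization of the deposited values, centring of each array on its median, a filter on probe sets below the median level, array weights, the replicate number as a block, leaving out each array in turn, leaving out genes on X or Y, a minimum log2 change of 1, 1 probe set per named gene, and both other list tests. The score on the leading axis as a covariate and leaving out the 3 arrays farthest out on it were chosen after the data were seen. The score is made from the same deviations from group means. As a covariate it therefore removes part of the spread by construction, which can raise counts of calls. Every split of the arrays of a contrast into groups of the same sizes was also fitted, or 100 random splits where there were more.

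The procedure was tested on simulated data with 21893 probe sets, of which 200 were changed. At 2 days it recovered 41.8%, 89.6% and 100% of the probe sets changed by log2 0.5, 1 and 2, and called 14 unchanged ones. At 3 months it recovered 32.8%, 85.1% and 98.5%, and called 9 unchanged ones. A simulated list shifted by -0.5 was called (adjusted p = 1.91e-36, and 1.85e-05 with an estimated correlation), and 0 other lists were. The simulated noise was drawn for each probe set alone, so genes of a list did not move together as they may on real arrays. The simulation therefore does not tell how often shared movement of genes gives a false list call. Tables were prepared with Python 3.11.15 and figures drawn with matplotlib 3.10.9.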

Results

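Gene expression was measured in biceps femoris muscle of 13 German Landrace pigs, with 1 whole-transcript array per animal. The groups were 4 dystrophin knockout (DMD KO) and 3 wild-type (WT) animals at 2 days of age, and 3 DMD KO and 3 WT animals at 3 months. The knockout animals lacked exon 52 of DMD, the gene for dystrophin, the protein that ties the cytoskeleton of the muscle fibre to the matrix around it. They were made by nuclear transfer from kidney cells edited with a modified bacterial artificial chromosome. Muscle of DMD KO animals was taken directly after their own death and that of WT animals after euthanasia, so every genotype difference given here is also a difference in manner of death and in cloning. The deposited table held 21893 probe sets with values from 2.81 to 13.8, read as log2 levels from their range, since the labels do not give the log base. The medians of the arrays lay between 7.32 and 7.38, and the number of arrays limits the precision of every value.

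The arrays of a group were not equally close to one another. WT replicate 3 at 2 days stood farthest from the rest, with a mean correlation across probe sets of 0.918 to the other arrays. The leading axis of the spread within groups held 44.9% of that spread, and the same array scored highest on it, at 61.1. The mean scores also differed between genotypes, at -13.1 and 18.0 in DMD KO and WT at 2 days and at -12.5 and 11.98 at 3 months, a difference that was not tested. The scores of WT replicates 1 to 3 at 2 days were 3.74, -10.9 and 61.1, so that mean rests on replicate 3. Arrays of the genotypes overlapped on the axis at both ages. Arrays with higher scores tended to have lower 95th percentiles, from 9.21 on the array with the highest score to 9.83 on that with the lowest.

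**Figure D1:**
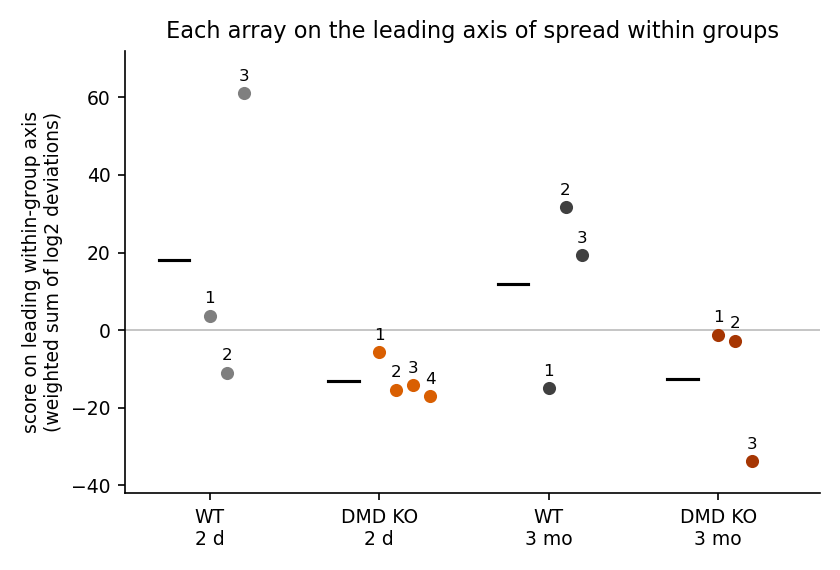
Score of each of the 13 arrays on the leading axis of the spread within groups (vertical axis, weighted sum of log2 deviations), by group, with replicate numbers beside the points and the group mean as a short line. WT replicate 3 at 2 days scored 61.1, WT replicates 2 and 3 at 3 months scored 31.6 and 19.2, and DMD KO replicate 3 at 3 months scored -33.7.

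DMD itself was not called between genotypes at either age. Its brighter probe set (15336155) had a mean log2 level of 12.18 ± 0.10 (SD, n = 4) in DMD KO and 12.07 ± 0.47 (SD, n = 3) in WT at 2 days, a difference of 0.11 ± 0.17 (SE, adjusted p = 0.705). At 3 months the difference was -0.22 ± 0.18 (SE, adjusted p = 0.528), with a 95% interval from -0.62 to 0.17. The other DMD probe set (15336160) differed by 0.23 (adjusted p = 0.423) and 0.00 (adjusted p = 0.996). Where these probe sets lie against the deleted exon is not given in the sources used here, and a probe set outside that exon says nothing of whether the exon is missing. Utrophin (UTRN), the close relative of dystrophin, differed by 0.16 at 2 days (adjusted p = 0.582) and by 0.52 ± 0.19 at 3 months (adjusted p = 0.145).

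Of the 8 measured members of the dystrophin complex list, a pair passed the test at 2 days, 3 passed at 3 months, and the list itself was not called at either age (adjusted p = 0.173 and 0.888). LAMA2, the laminin chain of the muscle basement membrane, was higher in DMD KO at both ages, by 1.09 ± 0.25 at 2 days (adjusted p = 0.0191) and 1.36 ± 0.27 at 3 months (adjusted p = 0.0105). Sarcospan (SSPN) was higher at 2 days by 0.61 (adjusted p = 0.0383) and differed by -0.60 at 3 months without passing (adjusted p = 0.0765), and its genotype difference itself differed between ages (-1.21, adjusted p = 0.013). At 3 months SGCE, the epsilon-sarcoglycan, was higher by 1.24 (adjusted p = 0.000723) and SNTB1, the beta-1-syntrophin, was lower at -0.76 (adjusted p = 0.00216). SGCA and SGCB, the alpha- and beta-sarcoglycans, did not pass at either age. Adjusted over the list alone, 2 members were higher at 2 days, and 3 were higher and 3 lower at 3 months.

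**Figure D2:**
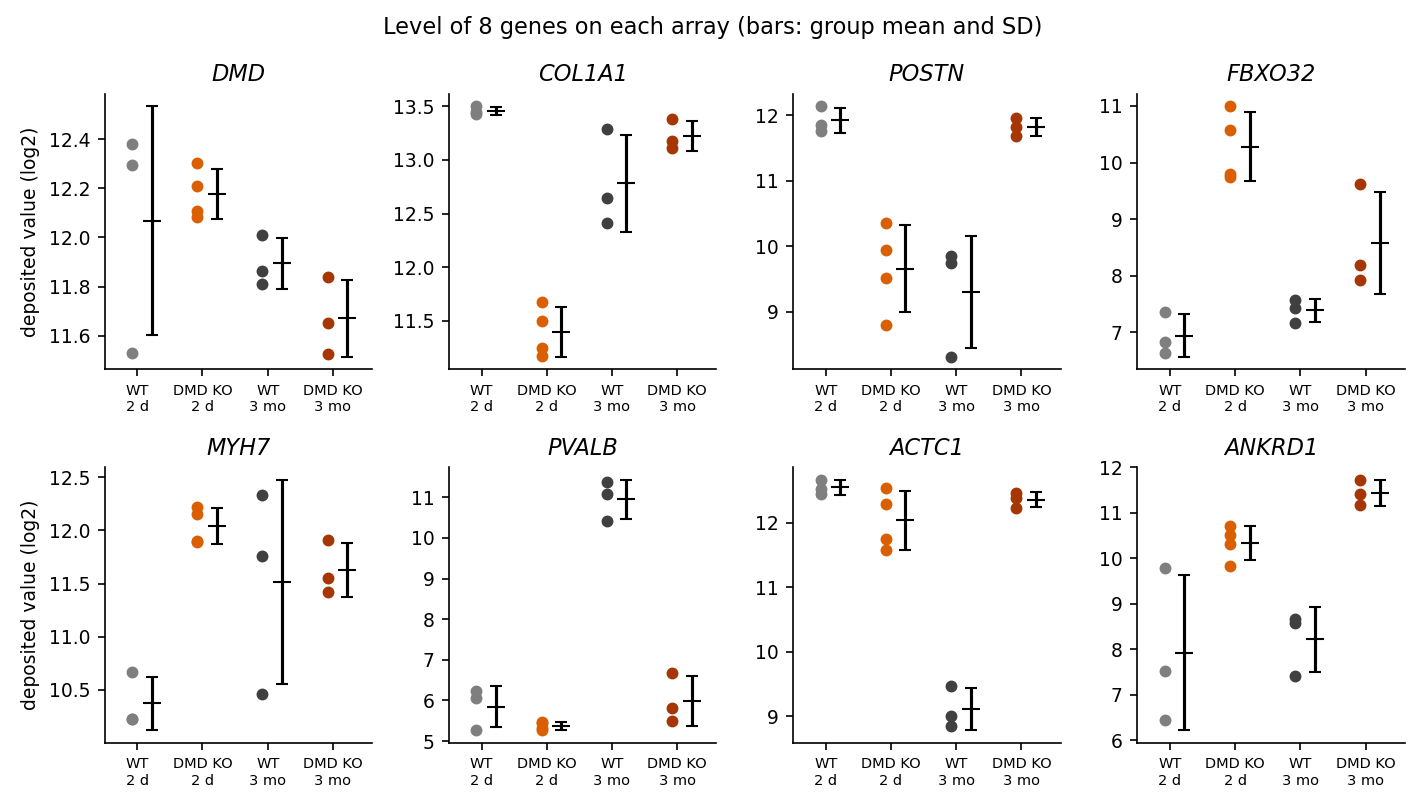
Deposited value (vertical axis, log2) of 8 genes on each array, by genotype and age, with the group mean and SD as bars. DMD lay between 11.5 and 12.4 on all 13 arrays, with the groups overlapping at both ages.

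The comparison of DMD KO with WT at 2 days asks how newborn muscle differs in the knockout. FBXO32 (atrogin-1), the muscle ubiquitin ligase of atrophy, was the gene with the highest rise, 10.1-fold higher in the 4 DMD KO animals than in the 3 WT animals (3.34 ± 0.39, SE, adjusted p = 0.000562). FMO1, a flavin-containing monooxygenase, was 6.78-fold higher, and RETREG1, a receptor for autophagy of the endoplasmic reticulum, 6.15-fold. GABARAPL1, a protein of the autophagosome membrane, was 6.06-fold higher, and SPP1 (osteopontin), a secreted matrix and inflammation protein, 5.99-fold (2.58 ± 0.17, SE, adjusted p = 1.51e-05). The gene with the deepest fall was KERA (keratocan), a proteoglycan of dense connective tissue, lower in DMD KO by a log2 difference of -3.50 ± 0.56 (SE, adjusted p = 0.00264), with a mean level of 6.04 in DMD KO. Signal over background was not analysed here, and no fold is given for a gene whose lower group had a mean below the 25th percentiles of the arrays (6.53 to 6.61). The matrix protein periostin (POSTN) was 4.81-fold lower and COL1A1, the main chain of collagen I, 4.17-fold lower (-2.06 ± 0.18, SE, adjusted p = 0.000179).

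The other genes among the 10 largest rises were LOC100516643 (2.62), LOC396711 (2.51), ANKRD1 (2.42), a stretch-responsive protein of the sarcomere, ARRDC3 (2.37) and NPR3 (2.24), the clearance receptor for natriuretic peptides. The mean of LOC100516643 in WT was 6.13. The other large falls were PCLAF (-2.36), a factor bound to the DNA replication clamp, GADL1 (-2.35), a decarboxylase of amino acids, NREP (-2.23), PSAT1 (-2.15), an enzyme of serine synthesis, COL15A1 (-2.11), AMPD1 (-2.09), the AMP deaminase of muscle, and ASPN (-2.05), a small matrix proteoglycan. In DMD KO the means of PCLAF and PSAT1 were 5.58 and 5.95, and that of GADL1 lay below those percentiles too. For each of these genes the values of the 4 DMD KO and the 3 WT arrays did not overlap, which was a condition of naming them. For ANKRD1 they nearly met, at 9.78, 6.45 and 7.52 in WT replicates 1 to 3 and 9.82 in DMD KO replicate 1, the lowest of its group. Its difference thus rests on WT replicates 2 and 3.

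Extracellular matrix genes were lower in DMD KO at 2 days. Of 30 measured members 19 fell and 2 rose, or 22 and 2 adjusted over the list alone, with a median log2 difference of -0.77 (list test adjusted p = 3.05e-11, and adjusted p = 0.0239 with an estimated correlation, the one list called at this age under that setting). COL15A1 and POSTN were among the falls, and SPP1 and THBS1 (0.77), a thrombospondin, were the 2 that rose. Tendon and cartilage markers were also lower, with 4 of 10 falling (7 adjusted over the list alone), among them KERA and the collagen-binding proteoglycan FMOD (-1.84). That list's call (adjusted p = 0.000358) was lost with the other setting (adjusted p = 0.342 with an estimated correlation). Fibroblast markers were not called (median -0.16, adjusted p = 0.0765).

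Genes of cholesterol synthesis and of cell division were lower as well. In the cholesterol list 8 of 11 genes fell (9 adjusted over the list alone), with a median of -0.75 (adjusted p = 5.76e-08, and adjusted p = 0.223 with an estimated correlation). The largest falls were in MSMO1 (-1.93), SQLE (-1.91), SC5D (-1.70) and CYP51 (-1.48), all enzymes of the pathway. In the cell cycle list 9 of 14 fell (11 lower and 1 higher adjusted over the list alone), with a median of -0.66 (adjusted p = 4.9e-05, and adjusted p = 0.342 with an estimated correlation). Among probe sets above the median level its median was -0.30 (adjusted p = 0.0768). TOP2A, the topoisomerase of dividing cells, fell by 1.78 and KIF11, a spindle motor, fell by 1.64. In DMD KO the means of KIF11, SQLE, SC5D and MSTN (5.49, 6.51, 6.57 and 6.42) lay below or among the 25th percentiles of the arrays. Of 14 adipocyte markers 3 fell (5 adjusted over the list alone), among them SCD (-1.83), the stearoyl-CoA desaturase, and DGAT2 (-0.86), an enzyme of triglyceride synthesis. Its adjusted p of 0.00406 became 0.342 with an estimated correlation and 0.0548 with the axis score as a covariate, a setting chosen after the data were seen, and its median of -0.21 was -0.12 with that covariate and -0.13 without WT replicate 3. In the list of myostatin and TGF-beta family signalling 1 of 12 genes fell (1 adjusted over the list alone), myostatin itself (MSTN), the brake on muscle growth, at -1.46. Its adjusted p of 0.0466 became 0.342 with an estimated correlation and 0.0753 with the axis score as a covariate (median -0.10 against -0.19), and it was 0.0528 and 0.058 without DMD KO replicates 1 and 2 and 0.0799 and 0.1 without WT replicates 1 and 2.

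Slow-fibre genes were higher and fast-fibre genes lower in DMD KO at 2 days. Of 9 slow-fibre genes 4 rose (8 adjusted over the list alone), with a median of 0.91 (adjusted p = 0.000358, and adjusted p = 0.342 with an estimated correlation). They were LMOD2 (1.91), a regulator of thin filament length, MYH7 (1.67), the slow myosin heavy chain, TNNC1 (1.21), the slow troponin C, and CASQ2 (0.91), a calcium store protein of the sarcoplasmic reticulum. Of 11 fast-fibre genes 4 fell (4 lower and 1 higher adjusted over the list alone), with a median of -0.21 (adjusted p = 0.00987, and adjusted p = 0.473 with an estimated correlation). These were MYBPC2 (-1.13), MYH1 (-0.91), ACTN3 (-0.75) and CASQ1 (-0.41). That list had adjusted p = 0.0799 without WT replicate 1, and its median was -0.34 without WT replicate 2. Among 16 genes of sarcomere and Z-disc structure 8 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.49 (adjusted p = 8.56e-05, and adjusted p = 0.342 with an estimated correlation). ANKRD1, FLNC (0.96), the filamin of muscle, and ACTN2 (0.85), the main actinin of the Z-disc, rose, and MYOM2 (-0.92), a protein of the M-band, fell. In ANKRD1 WT replicate 1 lay close to the DMD KO values.

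Genes of protein breakdown were higher. Of 12 atrophy and proteasome genes 4 rose (7 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.00588, and adjusted p = 0.342 with an estimated correlation). The median was 0.34 without WT replicate 3, 0.29 with the axis score as a covariate and 0.25 with array weights (adjusted p = 0.073). Beside FBXO32 these were FBXO30 (1.49), a ubiquitin ligase, FOXO3 (1.48), the transcription factor upstream of atrophy genes, and the proteasome subunit PSMB4 (0.65). Of 18 autophagy and lysosome genes 5 rose (5 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.03, and adjusted p = 0.342 with an estimated correlation). GABARAPL1, MAP1LC3B (1.05), a marker of autophagosomes, the cargo receptor SQSTM1 (0.95) and the protease CTSL (0.49) were among them, and the list had adjusted p = 0.0746 and 0.1 without WT replicates 1 and 2 and a median of 0.10 with the axis score as a covariate.

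Lists of the respiratory chain, the citric acid cycle, the PGC-1 network and ribosomal proteins were also called higher, and the lists of mitochondrially encoded genes (adjusted p = 0.315) and fatty acid oxidation (adjusted p = 0.995) were not called. In respiratory chain complex I 5 of 30 genes rose (9 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.00466, and adjusted p = 0.342 with an estimated correlation), led by NDUFA1 (1.24). Of 18 genes of complexes II to V 3 rose (11 higher and 1 lower adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0103, and adjusted p = 0.525 with an estimated correlation), and of 14 citric acid cycle genes 4 rose (4 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.0155, and adjusted p = 0.519 with an estimated correlation). ATP5H (0.77), a subunit of ATP synthase, and IDH3B (0.70), of isocitrate dehydrogenase, rose most. Of 10 genes of the PGC-1 network 3 rose (5 higher and 1 lower adjusted over the list alone), SIRT1 (0.95) by most, with a list adjusted p of 0.0466 that became 0.342 with an estimated correlation. With the axis score as a covariate the medians of complexes II to V, the citric acid cycle and the PGC-1 network were 0.21, 0.05 and 0.20 (adjusted p = 0.0928, 0.23 and 0.0891). Without WT replicate 3 at 2 days they were 0.22, 0.08 and 0.23 (adjusted p = 0.0609, 0.122 and 0.103). The PGC-1 call also ended without any 1 of 6 other arrays, with adjusted p from 0.0505 to 0.0697. After repeated quantile normalization the medians of complex I, complexes II to V and the citric acid cycle were 0.04, 0.16 and 0.04 (adjusted p = 0.185, 0.185 and 0.286). Of 18 cytosolic ribosomal proteins 9 rose (13 adjusted over the list alone), with a median of 0.35 (adjusted p = 1.93e-06, and adjusted p = 0.342 with an estimated correlation), among them RPS13 (0.66) and RPL10A (0.51).

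Among immune lists those of complement and interferon were called at 2 days. Of 10 complement genes 3 rose (3 adjusted over the list alone), the proteases C1S (1.18) and C1R (0.66) and the complement inhibitor CD59 (0.91), with a list adjusted p of 0.0233 that became 0.342 with an estimated correlation and 0.1 without WT replicate 2. Its median of 0.26 was 0.16 with the axis score as a covariate. The interferon list was called (median 0.47, adjusted p = 0.03, and adjusted p = 0.691 with an estimated correlation) though 0 of its 21 genes passed, over all genes or adjusted over the list alone. Its mean level was 8.20 and 8.32 in DMD KO replicates 2 and 4, 7.06 and 6.88 in replicates 1 and 3, and 6.55, 6.85 and 7.56 in the 3 WT animals. The median was 0.27 and 0.26 without DMD KO replicates 2 and 4 (adjusted p = 0.202 and 0.137), 0.31 and 0.39 without WT replicates 1 and 2 (adjusted p = 0.226 and 0.164), and 0.74 and 0.78 without DMD KO replicate 3 and WT replicate 3. CXCL10 differed by 1.56 (adjusted p = 0.332) and IFIT1 by 1.43 (adjusted p = 0.155). Lists for macrophages (adjusted p = 0.949), T and NK cells (0.125), neutrophils (0.597) and red blood cells (0.995) were not called.

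By limma 2175 of 21893 probe sets passed at 2 days, 1552 higher and 623 lower in DMD KO, and 1170 named genes were among them (829 higher and 341 lower). Of 44 gene lists 18 were called, 11 higher and 7 lower, and 1 of these with an estimated correlation. Of the 18 calls 10 held whichever 1 array was left out. The count of probe sets was 1302, 1284 and 1143 without DMD KO replicates 2, 3 and 4 and 1211 without WT replicate 3, and other splits of the same arrays called at most 1 probe set but up to 16 lists. Of the called probe sets 71.4% were higher in DMD KO, against 53.7% with the axis score as a covariate (996 higher and 860 lower).

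The same comparison at 3 months asks how muscle differs once the animals have grown. PVALB (parvalbumin), the calcium buffer of fast fibres, was lower in the 3 DMD KO animals than in the 3 WT animals by a log2 difference of -4.96 ± 0.32 (SE, adjusted p = 4.82e-06). Its mean level was 5.99 in DMD KO, below the 25th percentiles of the arrays (6.53 to 6.61), and 10.95 in WT. PDK4, the kinase that inhibits pyruvate dehydrogenase, was 12.6-fold higher (3.66 ± 0.61, SE, adjusted p = 0.00322), and ACTC1, the cardiac actin that developing muscle also makes, 9.49-fold higher (3.25 ± 0.23, SE, adjusted p = 8.16e-06). Lysozyme (LYZ), an enzyme of macrophages, was higher by 3.54 and the macrophage scavenger receptor MSR1 by 3.10, from WT means of 6.42 and 6.29, also below those percentiles. ANKRD1 and SPP1 were 9.35-fold and 8.01-fold higher, and CASQ2 was higher by 3.46 ± 0.25 (SE).

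The rest of the 10 largest rises were IL18 (3.15), an inflammatory cytokine, LOC396711 (3.14) and P2RY12 (3.05), a purine receptor of platelets and microglia. The next falls after PVALB were GADL1 (-1.95), FRZB (-1.94), a Wnt antagonist, TEX9 (-1.81), AK1 (-1.74), the adenylate kinase of muscle, and PFKFB1 (-1.73), which makes the activator of phosphofructokinase. FBXO40 (-1.68), a muscle F-box protein, PSTPIP2 (-1.58), PTER (-1.52) and FMO2 (-1.47) followed. The mean of IL18 in WT was 6.53 and that of FMO2 in DMD KO 6.08. Values of the 3 DMD KO and the 3 WT arrays did not overlap for any of these genes, again by the rule.

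Extracellular matrix genes were higher in DMD KO at 3 months, opposite to 2 days. Of 30 genes 23 rose and 0 fell (26 higher and 1 lower adjusted over the list alone), with a median of 0.83 (adjusted p = 6.95e-24, and adjusted p = 0.00144 with an estimated correlation). The largest were SPP1, POSTN (2.52), THBS1 (2.10) and the proteoglycan VCAN (2.09). Of 11 fibroblast and fibro-adipogenic progenitor markers 4 rose (6 higher and 1 lower adjusted over the list alone), with a median of 0.30 (adjusted p = 0.000337, and adjusted p = 0.121 with an estimated correlation). These were FAP (2.09), a surface protease of activated fibroblasts, the Wnt modulator SFRP2 (1.87), MEDAG (0.98) and FBLN1 (0.89).

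Macrophage and complement genes were higher. Of 20 macrophage markers 12 rose (12 adjusted over the list alone), with a median of 0.81 (adjusted p = 3.27e-10, and adjusted p = 0.109 with an estimated correlation). Beside LYZ and MSR1, the complement receptor VSIG4 (2.51) and the mannose receptor MRC1 (2.28) rose. Of 10 complement genes 8 rose (8 adjusted over the list alone), with a median of 0.82 (adjusted p = 2.8e-07, and adjusted p = 0.0279 with an estimated correlation), among them CFI (2.26), the complement factor I, and CLU (1.49), clusterin. In WT the means of VSIG4 and CFI (6.32 and 5.70) lay below the 25th percentiles of the arrays. Of 21 cytokines and chemokines 2 rose (4 adjusted over the list alone), IL18 and CXCL14 (1.56), and the list's adjusted p of 0.046 became 0.286 with an estimated correlation and 0.0658 without WT replicate 3 at 2 days. It was 0.0553 without WT replicate 2 at 2 days and, at 3 months, 0.0641 and 0.176 without DMD KO replicates 1 and 2 and 0.115 without WT replicate 1. The median of 0.11 was 0.02 without DMD KO replicate 2 and 0.19 without the 3 arrays farthest out. Lists for T and NK cells (adjusted p = 0.494), B cells (0.454), neutrophils (0.132) and red blood cells (0.558) were not called.

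Genes of muscle development and of membrane repair were higher. Of 12 regeneration and satellite cell genes 4 rose (5 adjusted over the list alone), with a median of 0.19 (adjusted p = 0.0016, and adjusted p = 0.109 with an estimated correlation). They were ACTC1, the adhesion molecule NCAM1 (1.37), the embryonic myosin light chain MYL4 (1.03) and CHRNG (0.51), the fetal subunit of the acetylcholine receptor. CHRNG was also the 1 of 6 neuromuscular junction genes that rose (3 adjusted over the list alone), and that list's adjusted p of 0.0398 became 0.159 with an estimated correlation and 0.0584 without WT replicate 3 at 2 days. It was 0.0572 and 0.075 without DMD KO replicates 1 and 2 at 3 months and 0.115 without WT replicate 1. Of 14 membrane repair genes 7 rose (7 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.0016, and adjusted p = 0.109 with an estimated correlation), led by the annexins ANXA2 (2.07) and ANXA1 (1.57), the annexin partner S100A11 (1.76) and myoferlin (MYOF, 1.56).

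Fast-fibre and energy genes were lower. Of 11 fast-fibre genes 4 fell (8 adjusted over the list alone), with a median of -0.52 (adjusted p = 2.4e-07, and adjusted p = 0.159 with an estimated correlation). Beside PVALB they were ACTN3 (-1.22), the calcium pump ATP2A1 (-0.95) and the fast troponin C, TNNC2 (-0.61). Of 22 genes of glycolysis and glycogen 7 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.45 (adjusted p = 1.54e-07, and adjusted p = 0.159 with an estimated correlation). PFKFB1, TPI1 (-1.24), PGAM2 (-1.10) and PGM1 (-1.03) fell, and the hexokinase HK2 rose (0.57). In complex I 8 of 30 genes fell (13 adjusted over the list alone), with a median of -0.36 (adjusted p = 1.12e-08, and adjusted p = 0.109 with an estimated correlation), among them NDUFB1 (-0.97) and NDUFB11 (-0.94). In complexes II to V 3 of 18 fell (7 adjusted over the list alone), with a median of -0.30 (adjusted p = 9.11e-05, and adjusted p = 0.31 with an estimated correlation), ATP5G1 (-0.84) by most. In the citric acid cycle 2 of 14 fell (4 adjusted over the list alone), PDHX (-0.65) and SUCLG1 (-0.48), with a median of -0.34 (adjusted p = 0.00144, and adjusted p = 0.351 with an estimated correlation). Of 12 calcium handling genes 2 fell and 1 rose (2 and 1 adjusted over the list alone), HRC (-0.81), CAMK2A (-0.63) and ASPH (0.52), with a list adjusted p of 0.00272 that became 0.109 with an estimated correlation. Its median of -0.30 was -0.18 without the 3 arrays farthest out. The mitochondrially encoded list (adjusted p = 0.342) and fatty acid oxidation (adjusted p = 0.149) were not called.

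Several further lists were called at 3 months. Of 18 autophagy and lysosome genes 7 rose (8 adjusted over the list alone), GABARAPL1 (1.72) and the protease CTSK (1.37) among them (adjusted p = 0.000337, and adjusted p = 0.151 with an estimated correlation). Of 17 unfolded protein response genes 5 rose and 1 fell (8 and 1 adjusted over the list alone), with a list adjusted p of 0.039 that became 0.31 with an estimated correlation and 0.0618 without WT replicate 3 at 2 days. It was 0.0681 and 0.0646 without DMD KO replicates 2 and 3 at 3 months, 0.0753 without WT replicate 1, and 0.151 without the 3 arrays farthest out on the axis. The chaperones HSPA5 (0.94) and CALR (0.81) rose, and ATF4, a transcription factor of the same response, fell by 1.01. Of 18 ribosomal proteins 2 rose (4 adjusted over the list alone), RPL3 (0.84) and RPL35 (0.33), with a list adjusted p of 0.000181 that became 0.31 with an estimated correlation. Endothelial markers were lower, with 1 of 10 falling (4 adjusted over the list alone), the VEGF receptor FLT1 (-0.57), and a list adjusted p of 0.0134 that became 0.31 with an estimated correlation. Its median of -0.21 was -0.10 without DMD KO replicate 3, -0.13 without WT replicate 2 and also with the axis score as a covariate, and -0.03 (adjusted p = 0.179) without the 3 arrays farthest out. Smooth muscle and pericyte markers were lower too, with 1 of 11 falling (2 adjusted over the list alone), RGS5 (-0.74), and a list adjusted p of 0.0117 that became 0.159 with an estimated correlation and 0.054 without WT replicate 1 at 3 months. Its median of -0.22 was -0.10 without DMD KO replicate 3 and also without the 3 arrays farthest out, where that of ribosomal proteins was 0.14 against 0.22.

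In 2 called lists 0 genes passed over all genes. In the cell cycle list (median 0.37, adjusted p = 0.0326, and adjusted p = 0.448 with an estimated correlation) 2 of 14 were higher adjusted over the list alone, and ANLN and KIF11 differed by 1.24 (adjusted p = 0.087) and 0.82 (adjusted p = 0.3). In the Schwann cell list (median -0.22, adjusted p = 0.0477, and adjusted p = 0.31 with an estimated correlation) 0 of 5 passed adjusted over the list alone, and NCMAP and SOX10 differed by -0.41 (adjusted p = 0.168) and -0.26 (adjusted p = 0.427). The adjusted p of these lists was 0.066 (median 0.20) and 0.215 with the axis score as a covariate, and without WT replicate 3 at 2 days it was 0.0573 and 0.0584. Without the 3 arrays farthest out the medians were 0.06 and -0.09 (adjusted p = 0.672 and 0.179). The cell cycle list had adjusted p = 0.29 without DMD KO replicate 3 (median 0.14) and 0.0571 without WT replicate 2, and the Schwann call ended without any 1 of 8 arrays. The lists of cholesterol synthesis (adjusted p = 0.251), atrophy (0.494), adipocytes (0.124), slow fibres (0.282) and tendon (0.428) were not called at 3 months.

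By limma 1310 probe sets passed at 3 months, 1012 higher and 298 lower in DMD KO, with 757 named genes among them (592 higher and 165 lower). Of 44 lists 21 were called, 12 higher and 9 lower, and 2 of these, extracellular matrix and complement, with an estimated correlation. Of the 21 calls 15 held whichever 1 array was left out. The count of probe sets was 2036 without WT replicate 3 at 2 days, which enters through the shared spread, 702 without DMD KO replicate 3, and 776 and 725 without WT replicates 2 and 3. The 10 splits of these arrays cannot give a share under 0.05, other splits called at most 2 probe sets but up to 23 lists, and with the axis score as a covariate 58.7% of called probe sets were higher (1117 higher and 787 lower), against 77.3% without it, so that the number called higher did not fall.

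**Figure D3:**
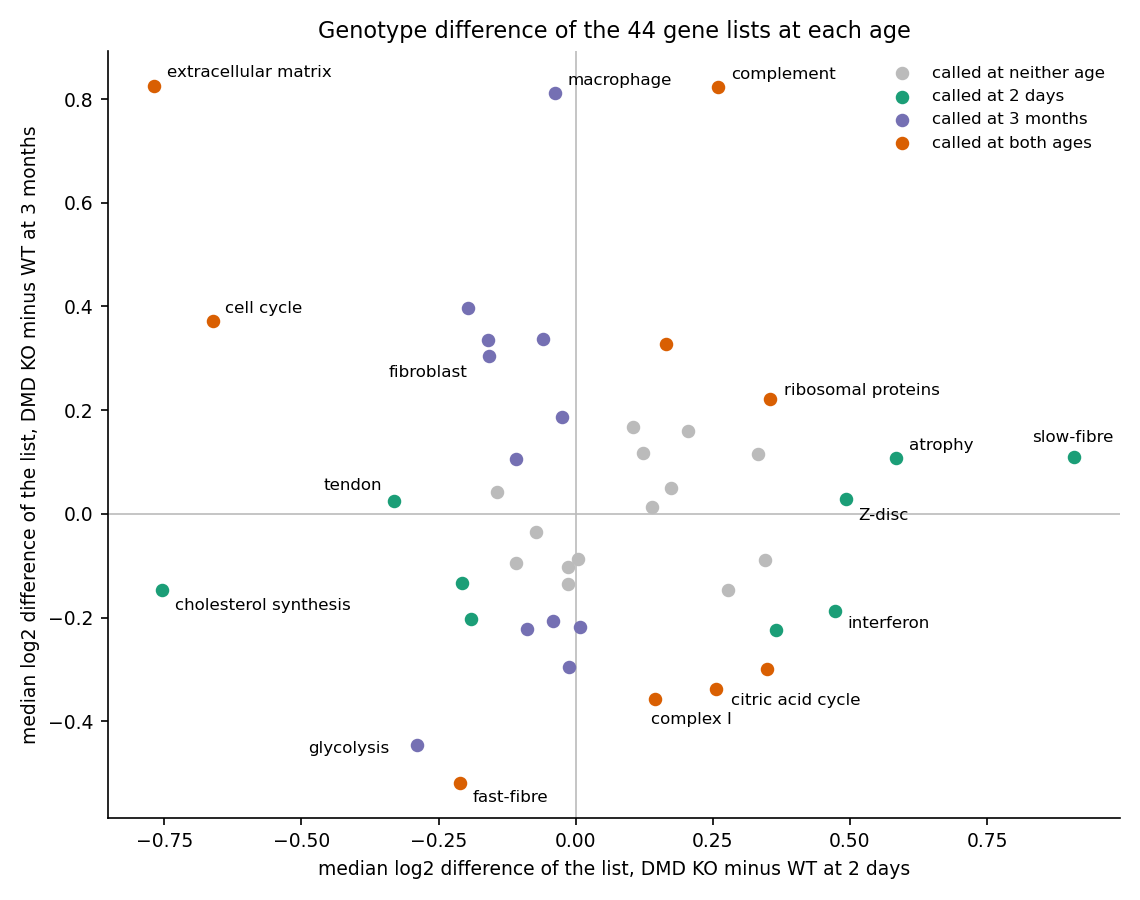
Median log2 difference between DMD KO and WT of each of the 44 gene lists at 2 days (horizontal axis) and at 3 months (vertical axis), with 1 point per list, coloured by the age at which the list test called it. Extracellular matrix genes sat at -0.77 at 2 days and 0.83 at 3 months, and fast-fibre genes were below 0 at both ages.

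Whether the genotype difference itself changed with age was tested by the interaction. The largest values were in KERA (5.18 ± 0.82, SE, adjusted p = 0.0031), POSTN (4.79), ASPN (4.13), LRRC17 (3.79) and ACTC1 (3.76) on the positive side, where the difference from WT was higher at 3 months than at 2 days. On the negative side were PVALB (-4.49 ± 0.43, SE, adjusted p = 0.000117), FMO1 (-3.14), TEX9 (-2.99), LOC100516643 (-2.65) and FMO2 (-2.59). For KERA and LRRC17 (DMD KO at 2 days, means 6.04 and 5.33), PVALB (all groups but WT at 3 months), LOC100516643 (WT at 2 days) and FMO2 (WT at 2 days, DMD KO at 3 months) a group lay below the 25th percentiles of the arrays. Signal over background was not analysed, so the size and order of these values are uncertain. The interaction of FBXO32 was -2.15 (adjusted p = 0.0489). Of 30 extracellular matrix genes 21 passed, all positive (26 adjusted over the list alone), with a median of 1.77 (adjusted p = 4.59e-37, and adjusted p = 0.000241 with an estimated correlation). VCAN (3.56) and fibronectin (FN1, 2.78) were among them.

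Lists of proliferation and lipid synthesis also had positive interactions. For cell cycle genes 5 of 14 passed (9 adjusted over the list alone), TOP2A (2.53) and ANLN (2.50) by most (adjusted p = 2.85e-07, and adjusted p = 0.114 with an estimated correlation). For cholesterol synthesis 2 of 11 passed (8 adjusted over the list alone), MSMO1 (2.04) and HSD17B7 (1.28), with a list adjusted p of 1.41e-05 that became 0.114 with an estimated correlation. For macrophage markers 9 of 20 passed (12 adjusted over the list alone), LYZ (2.78) and VSIG4 (2.46), both with 2 or more groups below the 25th percentiles, among them (adjusted p = 5.94e-11, and adjusted p = 0.0848 with an estimated correlation). Of the mitochondrial lists, fatty acid oxidation (adjusted p = 0.277) and the mitochondrially encoded genes (adjusted p = 0.892) had no called interaction. The citric acid cycle and the PGC-1 network had negative ones that were lost with an estimated correlation (adjusted p = 0.205 and 0.0848), and the PGC-1 median of -0.67 was -0.38 without WT replicate 3 at 2 days. Complex I and complexes II to V had negative ones too, with 11 of 30 complex I genes passing (17 adjusted over the list alone), NDUFB1 (-1.75) by most (adjusted p = 4.42e-12, and adjusted p = 0.0848 with an estimated correlation). In complexes II to V 7 of 18 passed (8 adjusted over the list alone), ATP5H (-1.22) by most (adjusted p = 2.85e-07, and adjusted p = 0.205 with an estimated correlation). By limma 1105 probe sets had an interaction, 669 positive and 436 negative, and 22 lists did, 12 positive and 10 negative, 1 of them with an estimated correlation, and 17 of the 22 calls held whichever 1 array was left out. The count of probe sets was 2566 with the axis score as a covariate, which takes part of the spread out by construction. Other splits called up to 913 probe sets and 21 lists.

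Across all 21893 probe sets the genotype differences at the 2 ages, which share no array, correlated with Pearson's r = 0.258 and Spearman's rho = 0.348, and across 10283 named genes with r = 0.212 and rho = 0.321. Genes are not independent replicates, and the jackknife SE over arrays of the first value was 0.182. The first value was 0.137 without WT replicate 3 at 2 days, 0.163 without DMD KO replicate 3 at 3 months, 0.0801 without the 3 arrays farthest out and 0.0353 with the axis score as a covariate, and 20 of 100 splits of the arrays gave a correlation as large. Of the called named genes 81 were higher at both ages, against 47.7 if the calls were independent, and 18 were lower at both, against 5.47. A further 68 genes were lower at 2 days and higher at 3 months, against 19.6, and 24 went the other way, against 13.3. The overlaps thus exceeded the counts for independent calls in opposite directions as well as in the same one. The calls at both ages share the estimate of the spread of each probe set, so the counts for independent calls are no measure of chance.

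In WT animals the comparison of 3 months with 2 days gives the change with growth. PVALB was higher at 3 months by a log2 difference of 5.11 ± 0.32 (SE, n = 3 per group, adjusted p = 1.46e-05), from a mean of 5.85 that lay below the 25th percentiles of the arrays, and CA3, the carbonic anhydrase of muscle, 10.8-fold higher. PDK4 was 19.8-fold lower (-4.30 ± 0.61, SE, adjusted p = 0.00284), ACTC1 10.8-fold lower and CASQ2 7.25-fold lower. The other large rises were PSTPIP2 (2.95), the ubiquitin ligase WWP1 (2.63), TEX9 (2.50), PGM2L1 (2.34), the phosphorylase kinase subunit PHKA1 (2.18) and PGM1 (2.12), a phosphoglucomutase. The other large falls were POSTN (-2.62), ENPEP (-2.09), an aminopeptidase, glycerol kinase (GK, -2.03), LOX (-1.86), which cross-links collagen, and ASPA (-1.83). At 3 months the means of ENPEP and GK in WT were 6.31 and 6.15, below the same percentiles. In the dystrophin complex SNTB1 (0.95) and SGCB (0.90) rose and SGCE fell by 0.93, while DMD differed by -0.17 (adjusted p = 0.834).

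Glycolytic and fast-fibre genes rose with age in WT. Of 22 genes of glycolysis and glycogen 13 rose (16 adjusted over the list alone), with a median of 0.98 (adjusted p = 2.83e-19, and adjusted p = 0.0579 with an estimated correlation), PFKFB1 (1.63) and PGAM2 (1.41) among them. Of 11 fast-fibre genes 7 rose (9 adjusted over the list alone), ACTN3 (2.02) and MYBPC2 (1.53) among them, with a median of 0.60 (adjusted p = 2.29e-12, and adjusted p = 0.141 with an estimated correlation). Extracellular matrix genes fell, 15 of 30 (19 adjusted over the list alone), with a median of -0.62 (adjusted p = 1.35e-18, and adjusted p = 0.00407 with an estimated correlation, the one list called under that setting). In cholesterol synthesis 3 of 11 genes fell (5 adjusted over the list alone), SQLE (-1.51) by most (adjusted p = 4.17e-06, and adjusted p = 0.193 with an estimated correlation). In the cell cycle list 1 of 14 fell (6 adjusted over the list alone), KIF20A (-0.50), with a list adjusted p of 4.82e-06 that became 0.204 with an estimated correlation. Of 19 genes of fatty acid oxidation 4 fell (7 adjusted over the list alone), ACSL1 (-1.33) and HADHA (-1.29) by most (adjusted p = 0.000593, and adjusted p = 0.243 with an estimated correlation). Of 9 imprinted and fetal growth genes 3 fell (4 adjusted over the list alone), MEST (-1.52), NNAT and SGCE, with a list adjusted p of 0.000593 that became 0.0579 with an estimated correlation. Of 12 antigen presentation genes 3 rose (5 adjusted over the list alone), among them SLA-DRA (1.78), a class II chain, and B2M (1.20), with a list adjusted p of 0.000829 that became 0.567 with an estimated correlation. Its median of 0.15 ran from 0.07 without WT replicate 1 at 2 days to 0.27 without WT replicate 3 at 3 months. The cholesterol median of -0.49 was -0.25 without WT replicate 2 at 2 days, and that of fatty acid oxidation, -0.25, was -0.47 without WT replicate 3 at 2 days and -0.50 without the 3 arrays farthest out.

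Among the other lists called with age in WT, 2 of 18 ribosomal proteins fell (5 adjusted over the list alone), RPL3 (-0.69) and RPL35 (-0.41), with a list adjusted p of 0.00237 that became 0.76 with an estimated correlation and 0.244 without WT replicate 1 at 2 days. Of 12 calcium handling genes 2 rose and 1 fell (5 and 1 adjusted over the list alone), HRC (0.93), CAMK2A (0.53) and ASPH (-0.85), with a list adjusted p of 0.0382 that became 0.204 with an estimated correlation and 0.0541 with the axis score as a covariate. It was 0.0681 and 0.154 without WT replicates 1 and 2 at 2 days and 0.111 without WT replicate 2 at 3 months, and the median of 0.21 was 0.10 without the 3 arrays farthest out. Of 16 sarcomere and Z-disc genes 1 rose (4 higher and 2 lower adjusted over the list alone), ACTA1 (0.54), the actin of skeletal muscle. That list's adjusted p of 0.0466 became 0.765 with an estimated correlation, 0.105 with the axis score as a covariate, 0.326 without WT replicate 3 at 2 days and 0.333 without WT replicate 2 at 3 months. It was 0.154 without WT replicate 2 at 2 days, 0.0912 without WT replicate 1 at 3 months and 0.0501 without DMD KO replicate 4 at 2 days, and the median of 0.15 ran from 0.08 to 0.26, and was 0.05 without the 3 arrays farthest out (adjusted p = 0.619). The interferon and adipocyte lists were called with 0 genes passing over all genes or adjusted over the list alone (adjusted p = 0.00914 and 0.00461, and adjusted p = 0.765 and 0.602 with an estimated correlation). CXCL10 differed by 2.41 (adjusted p = 0.372) and PPARG, the master regulator of fat cells, by -1.11 (adjusted p = 0.111), and the adipocyte list had adjusted p = 0.127 without WT replicate 3 at 2 days, with a median of -0.10 against -0.20. The interferon median of 0.39 was 0.13 without WT replicate 1 at 2 days (adjusted p = 0.244) and without WT replicate 2 at 3 months (adjusted p = 0.36), 0.32 without WT replicate 2 at 2 days (adjusted p = 0.107), and 0.85 and 0.74 without WT replicate 3 at 2 days and at 3 months.

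By limma 633 probe sets passed with age in WT, 375 higher and 258 lower at 3 months, and 13 of 44 lists, 6 higher and 7 lower, of which 8 held whichever 1 array was left out. Without WT replicate 3 at 3 months the count was 368, and from the 6 WT arrays alone it was 40, while 1 other split of these arrays, which set WT replicate 3 at 2 days and WT replicates 2 and 3 at 3 months apart from the rest, gave 1117 probe sets. Calls were more often lower than higher without WT replicate 3 at 2 days (288 higher and 469 lower) and without WT replicate 1 at 3 months (193 and 256).

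In DMD KO animals matrix, fibroblast and macrophage genes rose from 2 days to 3 months. The examples given here are genes named in the other comparisons, chosen after their values were seen. Of 30 extracellular matrix genes 25 rose (27 adjusted over the list alone), POSTN (2.17) and COL1A1 (1.83) among them, with a median of 1.11 (adjusted p = 3.89e-29, and adjusted p = 0.000649 with an estimated correlation). Of 11 fibroblast markers 7 rose (7 adjusted over the list alone), SFRP2 (1.98) by most (adjusted p = 4.53e-06, and adjusted p = 0.0347 with an estimated correlation). Of 20 macrophage markers 13 rose (14 adjusted over the list alone), LYZ by 3.26 ± 0.33 (SE, n = 4 and 3), with a list adjusted p of 1.34e-15 and adjusted p = 0.033 with an estimated correlation. Of 14 membrane repair genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a list adjusted p of 4.91e-06 and adjusted p = 0.033 with an estimated correlation. In the dystrophin complex SSPN fell by 1.37 (adjusted p = 0.000263) and SNTB1 rose by 0.46 (adjusted p = 0.0219), while DMD differed by -0.50 ± 0.17 (SE, adjusted p = 0.105).

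Genes of the respiratory chain and the citric acid cycle fell with age in DMD KO, and the list of mitochondrially encoded genes was not called (adjusted p = 0.0833). In complex I 15 of 30 fell (22 adjusted over the list alone), with a median of -0.45 (adjusted p = 1.43e-14, and adjusted p = 0.033 with an estimated correlation). In complexes II to V 14 of 18 fell (15 adjusted over the list alone), ATP5H (-0.87) and COX5B (-0.94) among them (adjusted p = 6.4e-15, and adjusted p = 0.0638 with an estimated correlation). In the citric acid cycle 8 of 14 fell (12 adjusted over the list alone), with a list adjusted p of 1.47e-09 that became 0.095 with an estimated correlation. Glycolysis genes went both ways, 13 of 22 rising and 3 falling (13 and 5 adjusted over the list alone), PGM1 (1.45) among the rises (adjusted p = 0.000116, and adjusted p = 0.238 with an estimated correlation). By limma 1760 probe sets passed, 979 higher and 781 lower at 3 months, and 24 of 44 lists, 14 higher and 10 lower. With an estimated correlation 9 of these lists were called, and not all 9 are named here. With the axis score as a covariate, which takes part of the spread out by construction, the count of probe sets was 3253. Of 35 splits of these arrays 4 called as many lists, up to 28. The age effects in WT and DMD KO, which share no array, correlated across probe sets with r = 0.0712 and Spearman's rho = -0.0184. With age 52 named genes rose in both genotypes, against 11.3 if the calls were independent, and 25 fell in both, against 5.94. A further 54 were called in opposite directions, against 16.4. These calls share the estimate of the spread too, so the counts for independent calls are again no measure of chance.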

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

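The tests of the age genes and the counts of splits were set before their results were seen, and the tests of the leading axis, of fibroblast content and of collection after death were chosen only after the results they concern were seen.

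Within the 4 DMD KO animals at 2 days, the only group large enough to test, 1 animal stood apart from the other 3 by Dixon's ratio in 6 of the values tested, which were 85 genes, 8 array values and 18 list levels. Chance flags about 1 in 20, or 5.55 of them here. FBXO30 had a ratio of 0.84, with 11.4 in replicate 4 against 10.7 to 10.8 in the others. MYH1 had 0.919, with 11.2 in replicate 3 against 11.6. THRSP had 0.881, with 7.93 in replicate 1 against 7.63 to 7.67. The mean level of complement genes had 0.928, with 7.37 in replicate 1 against 7.52 to 7.53. Replicate 4 stood apart in its mean correlation with its own group (ratio 0.84, at 0.985 against 0.984) and in its residual SD (ratio 0.87, at 0.154 against 0.159 to 0.16).

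The genotype difference itself differed between the ages, by the interaction test, for 1105 probe sets and 22 lists. Among single genes the interaction was 5.18 for KERA, 4.79 for POSTN, 4.13 for ASPN, 3.79 for LRRC17 and 3.76 for ACTC1. It was -4.49 for PVALB, -3.14 for FMO1, -2.99 for TEX9, -2.65 for LOC100516643 and -2.59 for FMO2. In KERA, LRRC17, PVALB, LOC100516643 and FMO2 at least 1 group lay below the 25th percentiles of the arrays, and signal over background was not analysed, so these sizes are uncertain. Lists with a positive median were extracellular matrix (1.77), cholesterol synthesis (0.849), macrophage markers (0.778), cell cycle (0.768), the unfolded protein response (0.545), tendon and cartilage (0.502), fibroblast markers (0.434), neuromuscular junction (0.381), complement (0.332), regeneration (0.281), cytokines (0.255) and membrane repair (0.197). Those with a negative median were interferon-stimulated genes (-0.71), the PGC-1 network (-0.666), complexes II to V (-0.61), the citric acid cycle (-0.567), complex I (-0.553), glycolysis (-0.495), atrophy (-0.357), sarcomere and Z-disc (-0.353), endothelial markers (-0.315) and fast-fibre genes (-0.102). With the axis score as a covariate the fast-fibre and endothelial lists no longer passed (adjusted p = 0.0856 and 0.0596). Without WT replicate 3 at 2 days those lists, atrophy and neuromuscular junction did not pass (0.0736, 0.0534, 0.0779 and 0.0536), and the median of the PGC-1 network was -0.376. That of cytokines was 0.161 without that array and 0.107 without DMD KO replicate 2 at 3 months. Without the 3 arrays farthest out fast-fibre, endothelial, neuromuscular junction and sarcomere lists did not (0.0884, 0.332, 0.0655 and 0.31), nor did interferon without WT replicate 1 at 2 days (0.0549) or WT replicate 2 at 3 months (0.0619). The interferon median was -0.518 and -0.349 in those fits, -0.471 without DMD KO replicate 2 at 2 days and -1.16 without WT replicate 3 at 3 months. Without the 3 arrays farthest out it was -0.454, and the median of complexes II to V was -0.406. The endothelial call ended in 5 of the 13 fits that left out 1 array (adjusted p up to 0.138), and the atrophy call in 2, the other being without DMD KO replicate 1 at 3 months. The fast-fibre call ended in 6 of the 13 fits that left out 1 array, and its median ran from -0.0271 to -0.203. Of the 22 calls 17 held whichever 1 array was left out, and with an estimated correlation only extracellular matrix was called (adjusted p = 0.000241). Adjusted p was then 0.0848 for macrophages, fibroblasts, complex I, the PGC-1 network and membrane repair, and 0.114 for regeneration, complement, cytokines, cell cycle, neuromuscular junction, tendon and cholesterol. It was 0.153 for the unfolded protein response, 0.205 for complexes II to V and the citric acid cycle, 0.347 for glycolysis, 0.396 for sarcomere, atrophy and endothelial lists, and 0.557 for interferon and fast-fibre genes.

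More probe sets were higher than lower in DMD KO at both ages, 71.4% of those called at 2 days and 77.3% at 3 months. With the score on the leading axis of the spread within groups as a covariate the shares were 53.7% and 58.7%. At 2 days the calls went from 1552 higher and 623 lower to 996 and 860, so part of the excess may be a spread that also separates animals of the same group. At 3 months they went from 1012 and 298 to 1117 and 787, where the number called higher did not fall, so the lower share does not tell whether the axis gives the excess. The score followed the bright end of an array's values, with high scores where the 95th percentile was low. That percentile was 9.21 on WT replicate 3 at 2 days (score 61.1) and 9.48 on WT replicate 2 at 3 months (31.6). It was 9.83 on DMD KO replicate 3 at 3 months (-33.7). What lies behind this was not tested. RNA quality, cell content and genotype itself remain open, since the mean scores also differed between the genotypes, though single arrays overlapped.

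Extracellular matrix genes were lower in DMD KO at 2 days and higher at 3 months. The tables argue against the leading axis as the whole cause, since the medians with the score as a covariate were -0.92 and 0.82. A different amount of connective tissue in the piece of muscle would move fibroblast markers alike. Among members above the median level (29 matrix and 9 fibroblast genes) the matrix genes at 2 days differed from the fibroblast markers by -0.625 (bootstrap 95% interval -0.906 to -0.148). The bootstrap drew genes and not animals, so its intervals hold no spread between animals. Tendon and cartilage markers were called lower at that age as well (4 of 10 genes, median -0.33, adjusted p = 0.000358), a call lost with an estimated correlation (adjusted p = 0.342), so a different amount of connective tissue remains open at 2 days, and so it does at 3 months with a difference of 0.531 (-0.797 to 1.11). Collection after death acting alike at both ages would cancel in the interaction, whose median was 1.77. Illness that differed between the ages and the genotype itself are both candidate explanations that the design cannot separate.

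Whether chance alone could group the animals so was examined with the other splits of the same arrays. At 2 days 1 of 35 splits, the real one, gave 2175 probe sets, with at most 1 in any other. Likewise 1 of 35 gave 18 lists, with at most 16 in any other. Both shares lay under 0.05, but 1 of 35 is the smallest share these splits can give. The shares were not adjusted for the number of such tests. For probe sets the real split stood far apart, while the margin for lists is smaller than the range of 13 to 20 when 1 array is left out. In the age comparison of DMD KO the real split also stood far apart for the 1760 probe sets (1 of 35 splits, highest other 2) but not for the 24 lists (4 of 35, highest other 28). For the interaction the real split gave the most probe sets, 1105 (1 of 100, highest other 913), and the most lists, 22 (1 of 100, highest other 21). Both margins are smaller than the ranges when 1 array is left out, 789 to 1265 and 18 to 25. These splits exchanged genotypes within each age, so they ask whether there is a genotype difference at all. They cannot tell whether that difference changed with age. The 10 splits of 3 arrays against 3 are too few for a share under 0.05. There, 1 split gave the 1310 probe sets at 3 months (highest other 2) and 2 gave as many as 21 lists (highest other 23). In WT with age 2 gave as many as 633 probe sets (highest other 1117, the split that follows the leading axis) and 1 gave 13 lists (highest other 11). For the correlation of 0.258 between the ages chance cannot be excluded, with 20 of 100 splits as large and a highest other of 0.575.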

How the results depend on the processing

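The fits with the axis score as a covariate and without the 3 arrays farthest out on that axis and the list test of age in DMD KO were chosen after the data were seen, and all other alternatives before. Counts of probe sets within 1.5 times the reported one were obtained with eBayes with trend and robust settings, repeated quantile normalization, centring, the filter on dim probe sets and the removal of genes on X or Y. Some list calls ended under alternative settings. Of the 18 at 2 days, 21 at 3 months, 13 for age in WT and 22 for the interaction, repeated quantile normalization ended 5, 2, 2 and 2. The filter on dim probe sets ended 7, 5, 3 and 5, array weights 5, 5, 2 and 5, a replicate block 2, 3, 1 and 1, and centring 1 at 2 days. Fits on the groups of a contrast alone ended 1 at 2 days and 5 at 3 months, and fry ended 3, 2, 5 and 6. Not every list that lost its call under these settings is named here. Of the 77 named genes at 2 days, 76 at 3 months and 45 for age in WT, 64, 74 and 43 kept their direction and their side of the threshold after quantile normalization, 58, 72 and 45 with the axis score, and 56, 76 and 42 without WT replicate 3 at 2 days.

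Fitting only the groups of a contrast gave 1275 probe sets at 2 days, 40 for age in WT and 2499 for age in DMD KO, and the cause was not tested. The residual SD was 0.154 to 0.16 on the DMD KO arrays and 0.176 to 0.305 on the WT arrays at 2 days. With 1 shared estimate of the spread, the calls for age in WT also rest on the DMD KO arrays. The fit on the groups alone kept 62 of 76 named genes at 3 months and 12 of 45 for age in WT. Array weights gave 5438 probe sets at 2 days, 3412 at 3 months, 2562 for age in WT, 3743 for age in DMD KO and 2760 for the interaction, and the cause was not tested. The weights were 4.73, 0.636 and 0.191 for WT replicates 1 to 3 at 2 days, so the weighted mean of that group rests largely on replicate 1. At 3 months the highest were 2.68 for DMD KO replicate 2 and 1.87 for WT replicate 3. With these weights the sarcomere and Z-disc list with age in WT turned to the lower direction by the list test, with a median of 0.0215 (adjusted p = 0.948, the highest over its alternatives), against 0.15. A replicate block gave 735, 829, 325, 1087 and 580 in the same order, a cause not tested, and kept 41 of 77, 62 of 76, 32 of 45 and, for the interaction, 47 of 70 named genes. The numbers do not pair the animals, since same-numbered arrays had deviations correlated between -0.495 and 0.33. A minimum log2 change of 1 gave 530, 453, 244, 544 and 681 by its construction. With 1 probe set per named gene the counts were 1335, 854, 385 and 1087 for the first 4 contrasts, out of fewer tests. An estimated correlation in the list test gave 1, 2, 1, 9 and 1 lists. The axis score as a covariate gave a correlation of 0.0353 between the ages, the cause being untested. It gave 1983 probe sets for age in WT, 3253 for age in DMD KO and 2566 for the interaction. It takes the leading 44.9% of the spread within groups out of the fit by construction, so these higher counts do not speak for the calls. At 2 days it gave 996 higher and 860 lower, and at 3 months 1117 and 787, against 1552 and 623, and 1012 and 298. Without the 3 arrays farthest out 55 of 77, 57 of 76 and 37 of 45 named genes were kept, and the split was 973 and 561 at 2 days, and 605 and 320 at 3 months.

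Leaving out 1 array at a time gave 1143 to 3210 probe sets at 2 days, 702 to 2036 at 3 months, 368 to 757 for age in WT, 1180 to 2294 for age in DMD KO and 789 to 1265 for the interaction. The 2-day count moved by over 1.5 times without DMD KO replicates 2 (1302), 3 (1284) and 4 (1143) and WT replicate 3 (1211) at 2 days. The 3-month count did so without WT replicate 3 at 2 days (2036), DMD KO replicate 3 (702), WT replicate 2 (776) and WT replicate 3 (725) at 3 months, and the WT age count without WT replicate 3 at 3 months (368). The WT age count was 288 higher and 469 lower without WT replicate 3 at 2 days, 193 and 256 without WT replicate 1 at 3 months, and 998 and 1564 with array weights, against 375 and 258. The causes were not tested. Called lists ranged over 13 to 20, 16 to 23, 10 to 15, 23 to 29 and 18 to 25, and the correlation over 0.137 to 0.318, with over 1.5 times less than 0.258 without WT replicate 3 at 2 days (0.137) and DMD KO replicate 3 at 3 months (0.163). Signal over background was not analysed here.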

Other observations

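The genes of the next 2 paragraphs were named after their values were seen, and of the tests below the one with the axis score as a covariate uses a setting chosen after the result was seen, while the tests themselves were written before.

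A group of genes was called in the same direction at both ages. Lower in DMD KO at 2 days and at 3 months were GADL1 (-2.35 and -1.95), the adenylate kinase AK1 (-1.63 and -1.74), myostatin (MSTN, -1.46 and -1.23), ACTN3 (-0.75 and -1.22), the actinin of fast fibres, and pyruvate kinase (PKM, -0.79 and -0.91). Higher at both ages were SPP1 (2.58 and 3.00), the sphingomyelinase relative SMPDL3A (2.15 and 2.46), the scramblase PLSCR4 (1.65 and 1.38), C1S (1.18 and 1.22), LAMA2 (1.09 and 1.36), the adhesion molecule VCAM1 (0.78 and 0.97) and the ferritin light chain FTL (0.92 and 0.97). None of these genes had a called interaction (adjusted p from 0.378 for ACTN3 to 0.978 for C1S), which does not show that they differed alike, and 20 of 100 splits of the arrays gave as large a correlation between the ages.

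At 2 days some genes were called in lists that were not called themselves. In the glucocorticoid response list (adjusted p = 0.0542) 4 of 11 genes were higher in DMD KO (4 adjusted over the list alone), FKBP5 (2.12), GLUL (1.88), SESN1 (1.60) and RGCC (1.56). In the glycolysis list (adjusted p = 0.375) 4 of 22 were higher and 6 lower (6 and 8 adjusted over the list alone). UGP2 (1.27), GYG1 (0.73) and GYS1 (0.54), which make glycogen, and the glucose carrier SLC2A4 (0.50) were the higher ones, and LDHA (-0.82), PKM (-0.79), TPI1 (-0.67) and PGK1 (-0.55), enzymes of glycolysis, were among the lower ones. In the heat shock list (adjusted p = 0.193) 4 of 17 were higher and 1 lower (7 and 3 adjusted over the list alone), HSPB1 (1.28) and CRYAB (1.14), both small chaperones of muscle, by most.

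In genes called with age in WT, DMD KO animals at 3 months lay toward the 2-day level. Of 342 such named genes 311 (90.9%) did so, by a median of 0.627 of the WT change (0.658 with the axis score as a covariate). The WT arrays at 3 months stand on both sides of this comparison, so a simulation with DMD KO equal to WT gave 65.9% (at most 69.7% in 20 runs) and a median of 0.0928, though over more age genes than in the data (888 against 342). Its noise was drawn for each probe set alone, while on the real arrays 1 axis held 44.9% of the spread within groups. The range over the runs may thus be too narrow. With each WT array held out in turn from the choice of genes and used alone for the comparison the share was 90.9%, 83.4% and 79.1% and the median 0.646, 0.408 and 0.529, against chance deviation of shared arrays as the whole cause. With the axis score as a covariate the share was 87.7% of 1127 genes. The WT arrays stood on both sides of that fit too, and no simulation was made with the covariate. The share that would have pointed to the axis was set below the 65.9% simulated without a difference. So the value of 87.7% does not decide for or against the leading axis. The set of age genes is itself uncertain, since it was called with a spread shared with the DMD KO arrays. The WT arrays alone called far fewer probe sets. Another split of the WT arrays called 1117 probe sets, against 633 in the real one. The genotype itself, slower growth and illness before death remain open as causes and were not tested.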
